A study of Arabidopsis thaliana with 24 samples.

How the data were processed

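The data are a table of 3439 array probes in 24 columns, 12 for the wild type and 12 for the sut2 mutant, total RNA in each case. Columns were assigned to groups and given their numbers from the titles in the labels. The deposited values are intensities on a linear scale. How the authors made them (image analysis, background correction, averaging of spots, scaling) is not given in the sources used here; from the deposited values, each column has a mean close to 1 (0.959 to 1.05), no value is below 0, and 20 of the columns hold values at a shared ceiling of 100, so the intensities appear scaled per array and limited at both ends. Whether a column is an array or a colour of an array, and which dye it carried, is likewise not given. Between 4.25% and 7.94% of the values of a column were 0. No measure of background or detection was used, so a dim probe cannot be told from background.

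Values below the 1st percentile of all positive values (0.00971) were set to it, log2 was taken, and the columns were quantile-normalized, because their median log2 values differed by more than 0.1 (the mean of the medians was 0.54 lower in the mutant). Quantile normalization gives all columns the same distribution, so a change of most transcripts in 1 direction would not be seen, and fold changes of probes with values at the floor are set partly by it. Probe names came from a platform annotation that can be old. Of the 3439 probes, 692 had 1 gene, 870 several and 1877 none; no gene was named from a probe with several. Symbols were updated through the gene numbers in a table of the TAIR10.1 assembly, where 690 of the 692 matched. No coordinates are given, since no build is named for the probes. The gene AT2G25870 had 2 probes, which disagreed (0.98 and -0.17 log2), and was represented by the brighter.

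The main test, chosen before the data were examined, was limma (version 3.58.1 in R 4.3.3) with lmFit and eBayes, mutant minus wild type, two-sided, on all 24 columns with group as the only term. Probes passed at a Benjamini-Hochberg adjusted p under 0.05 over all probes. Every adjusted p for a gene in the text is from limma. Named genes were those with 1 gene name and the 12 largest rises and 12 largest falls among the probes past the threshold, the measured members of the lists fixed beforehand, and of each list with at least 3 measured genes up to 4 members with the largest moderated t, 66 genes in all, of which 45 passed. Gene lists were tested on 1 probe per gene with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the planned and over the added lists separately. Added lists, 10 in number, were drawn up from the named genes before fold changes were seen. The 2 lists to be built from descriptions were not made, because the annotation used held symbols only.

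Because the groups share numbers, the deviations of each column from its group mean were correlated. All 12 pairs of columns with the same number in the 2 groups correlated by more than 0.1 (0.14 to 0.40, median 0.21), so the numbers pair the columns; the pairing comes from the data and not from a label. With the replicate number as a block 1477 probes passed, and the blocked value is given beside a gene only where it changed the call. Deviations of consecutive numbers within a group correlated by 0.12 to 0.55 (median 0.32), against a median of -0.01 for other numbers of the same 6 and -0.22 between numbers 1 to 6 and 7 to 12. Counts with consecutive numbers averaged within each group, 6 values against 6, were fixed before the data were examined and are given beside the main ones.

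The steps were tested on simulated data made from the means and variances of the 3439 probes, with 200 probes changed by a log2 of 0.5, 1 or 2 (5 simulations). Where all 24 columns were simulated as separate samples, the fit to 24 columns recovered 19.7%, 58.2% and 88.2% of the changed probes by size, and 4.20% of its calls were false. Where consecutive numbers were simulated as repeats of 1 sample, 31.7% of the calls from 24 columns were false, and 5.13% of those from the averaged values, which recovered 3.28%, 38.2% and 77.9%. Where such repeats also shared arrays between the groups, with 44.3% of the variance between sets in common, the false share was 8.90% in 24 columns, 20.6% with the replicate block, 1.53% in the averaged values and 5.16% in the averaged values with the block. This last simulation was added after the data were seen. All simulations drew the probes independently of each other. They held no effect of probe position, of dye or of the division of the numbers, so the false shares may not carry over to the data. A list of 20 genes raised by a log2 of 1 was found by camera in 5 of 5 simulations of either kind, with 0 of 100 random lists called. The lists tested in the data held 4 to 19 genes, of which not all changed. The simulations therefore do not show how often camera would find changes in those lists.

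Alternatives fixed beforehand were the number as a fixed or random block, no normalization, median centring, cyclic loess, a floor at the 5th percentile (0.0454), no floor (values of 0 left out, 6 values needed per group), leaving out the dimmest 25% or 50% of the probes, eBayes with trend and robust settings, array weights, averaging of consecutive numbers, of numbers 6 apart or of 4 consecutive numbers, and leaving out each column. Fits within numbers 1 to 6 and 7 to 12 or with this division as a block, the averaged sets with a block, fry with the block, on averaged values or without normalization, and removal of the position of a probe in the probe order were added after the data were seen. Figures were drawn with matplotlib 3.10.9.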

Results

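Transcript levels were measured by array in the sut2 mutant of Arabidopsis thaliana and in its wild type, both of the Wassilevskija ecotype. The labels describe the mutant as lacking SUT2, a protein of the plasma membrane known as a sucrose transporter or possible sucrose sensor; the loss itself was not measured here. The table held 12 columns of wild type and 12 of the mutant, numbered 1 to 12 in each group, and 3439 probes with a value in every column. The values were linear intensities with a column mean between 0.959 and 1.05, between 146 and 273 values listed at 0 in each column, and up to 4 values per column at the shared ceiling of 100. The median intensity was 0.372 ± 0.032 in wild type and 0.256 ± 0.020 in the mutant (SD, n = 12 columns each), while the mean intensity was 1.01 ± 0.023 and 0.985 ± 0.014, so before normalization the centre of the mutant columns was lower by more than their mean. The tissue and growth conditions, and whether the columns came from separate plants, are not given in the sources used here. The p-values therefore measure only the spread between these columns, which may be technical, and the number of arrays limits their precision.

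The comparison asks which transcripts differ between the sut2 mutant and wild type. None of the probes was named as SUT2, so the mutated gene itself gave no value here and could not serve as a check of the labels. Of the probes, 692 carried the name of 1 gene, 870 carried several names and 1877 carried none, and the 692 stood for 691 distinct genes. Only those 691 are named below.

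The mutant columns differed from the wild type columns at many probes, and after quantile normalization the falls were larger than the rises. The dye of each column is not given, so if the groups shared arrays, genotype and dye may not be separable. The largest named fall was that of AT4G18180, to 7.02-fold less than in wild type, and the largest named rise without a value listed at 0 was that of AT5G19210, by 3.07-fold. Of the 3439 probes, 1196 passed an adjusted p of 0.05 in the 24 columns, 648 of them higher and 548 lower in the mutant. The median log2 change was 0.70 among the higher and -1.08 among the lower probes. A log2 change of at least 1 was reached by 149 higher and 296 lower probes. Among the 691 named genes, 125 were higher and 102 lower. In the principal component analysis the groups lay apart within numbers 1 to 6 and within numbers 7 to 12, while the first component, with 24.1% of the variance, also moved with that division of the numbers.

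**Figure D1:**
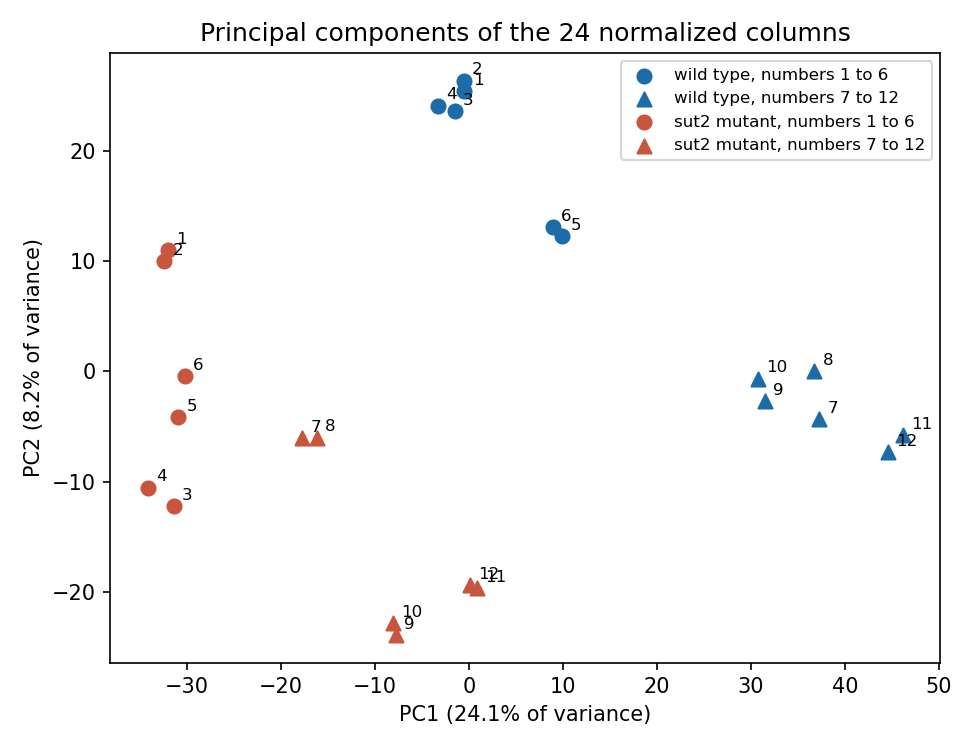
Principal components 1 (24.1% of variance) and 2 (8.2%) of the normalized log2 values, with 1 point per column labelled with its number. Colours give the groups and shapes the numbers 1 to 6 or 7 to 12; consecutive numbers of a group (1 and 2, 3 and 4 and so on) lie side by side.

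These counts depend on what the columns are. Columns with consecutive numbers in the same group resembled each other more than any other columns of the group. Averaging them, which leaves 6 values per group, reduced the count to 449 probes, 185 higher and 264 lower. Of these, 448 were among the 1196 with the same direction. With the averaged sets also paired across the groups by number, 759 probes passed, 354 higher and 405 lower. Within numbers 1 to 6 alone 663 columnwise calls were made and within numbers 7 to 12 alone 1099, and with this division as a block 1397 probes passed. With consecutive numbers averaged, which leaves 3 values per group in each division, 57 passed within numbers 1 to 6 (4 higher, 53 lower) and 259 within numbers 7 to 12 (79 higher, 180 lower). The split also moved with the scaling between columns. Without normalization 173 probes were higher and 1016 lower, and with each column centred on its median 1053 were higher and 506 lower. The median log2 change of all probes was 0.10 after quantile normalization, -0.24 without normalization and 0.31 with median centring. Of 45 named genes past the threshold, 17 lost the call without normalization and 2 more lost it with the sign turned. Changes are given below relative to the quantile-normalized values.

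The log2 change had the same sign in numbers 1 to 6 and in numbers 7 to 12 at 71.3% of all probes. Of the 663 probes called in numbers 1 to 6 alone, 609 (91.9%) had that sign in numbers 7 to 12, and of the 1099 called in numbers 7 to 12 alone, 992 (90.3%) had it in numbers 1 to 6. The direction was the same in all 6 sets of consecutive numbers at 29.7% of all probes, against 3.12% by chance, and at 831 of the 1196 (69.5%), whose selection over all columns favours this. The 3.12% takes the sets as independent and free of any shared bias. An effect of probe position, scaling or dye common to the sets would also raise the share. The gap therefore does not measure genotype alone. Across all probes, which are not independent replicates, the log2 changes of the 2 divisions correlated with r = 0.55 (Spearman 0.53). The change differed between the divisions by an adjusted p under 0.05 (limma interaction term) at 5 probes in the 24 columns and at 1 probe in the averaged values, where 257 had an unadjusted p under 0.05.

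**Figure D2:**
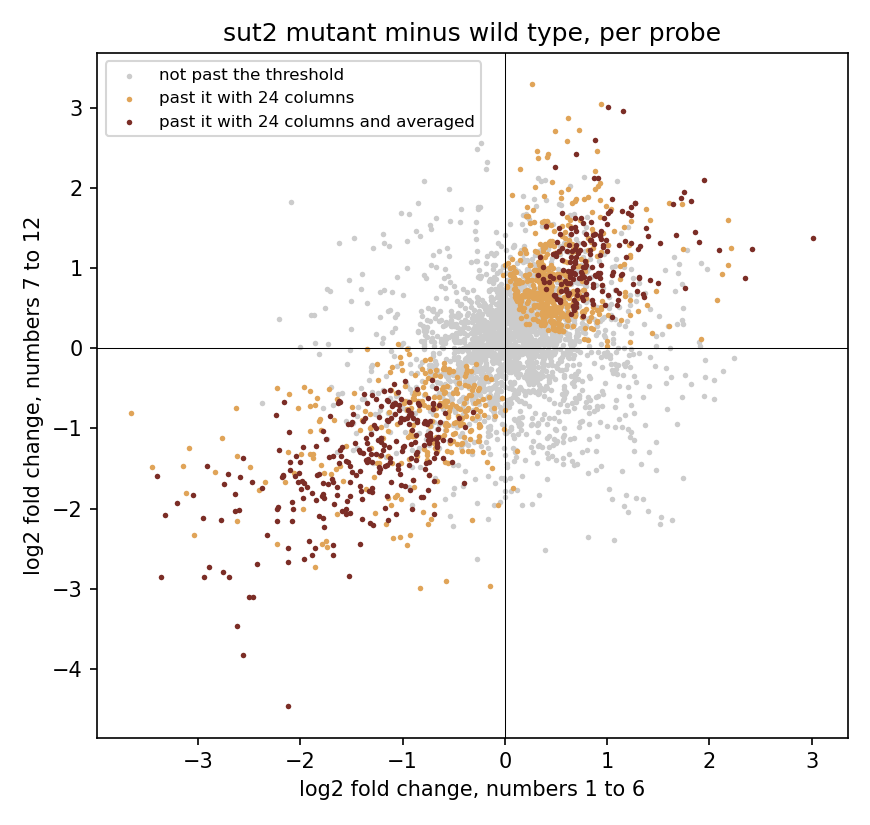
Log2 fold change (sut2 mutant minus wild type) of each of the 3439 probes in numbers 1 to 6 (horizontal) and in numbers 7 to 12 (vertical). Grey probes did not pass the threshold, orange probes passed it in the 24 columns, and dark red probes passed it in the 24 columns and with consecutive numbers averaged; 71.3% of all probes have the same sign on both axes.

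The 12 named genes with the largest falls dropped to between 4.49 and 7.02-fold below wild type, and 11 of them were lower in all 6 sets. Of the 12, 7 had 1 to 3 mutant values listed at 0 and none in wild type, so that the floor sets part of their folds. AT4G18180 fell from a mean log2 value of 1.21 ± 0.50 in wild type to -1.61 ± 0.50 in the mutant (SD, n = 12 columns), a log2 change of -2.81 ± 0.20 (SE, adjusted p = 2.36e-10), with all 12 numbers lower. With consecutive numbers averaged its SE was 0.28 and its adjusted p 9.93e-05, or 0.00070 with the averaged sets paired by number. SEs, adjusted p and counts over 12 numbers from the main fit treat every column as a separate value, which consecutive numbers may not be. AT1G29070, which encodes ribosomal protein L34 of the plastid, fell by 2.77 ± 0.47 (adjusted p = 0.00011), and by 1.90 without its 3 mutant values listed at 0 (adjusted p = 2.06e-05). AT5G39980, a pentatricopeptide repeat protein, fell by 2.53 ± 0.26 (adjusted p = 1.28e-07, 0.0017 averaged), and AT3G02690, a membrane protein of the EamA-like transporter family, by 2.46 ± 0.44 (adjusted p = 0.00017, 0.016 averaged). The DnaJ-domain protein AT5G06410 fell by 2.31 ± 0.51 (adjusted p = 0.0014). The others were AT5G19900, AT5G27560, AT1G44920, AT4G35660, AT1G33250, AT3G60590 and AT3G52550, with log2 changes from -2.78 to -2.17; AT4G35660 was higher in the mutant in 1 of the 6 sets. Without the values at 0 the log2 changes of AT5G27560 and AT3G52550 were -1.62 and -1.39 in place of -2.46 and -2.17, those of AT5G19900, AT3G02690, AT5G06410 and AT1G33250 lay between -2.29 and -1.66, and all 12 passed. With consecutive numbers averaged 8 of the 12 still passed; AT5G27560, AT1G44920, AT1G33250 and AT3G52550 did not, with adjusted p between 0.051 and 0.087. With the averaged sets paired by number 10 passed, all but AT1G33250 (adjusted p = 0.051) and AT3G52550 (adjusted p = 0.060).

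The 12 named genes with the largest rises increased by 2.71 to 3.72-fold, and 7 of them were higher in all 6 sets. Most were dim, with 10 of them listed at 0 in at least 1 wild type column, so that the floor sets part of their folds. AT5G05330, at 0 in 5 wild type columns, had a log2 change of 1.90 ± 0.57 (adjusted p = 0.013), of 0.91 with a floor at the 5th percentile (adjusted p = 0.022) and of 1.27 without the values at 0 (adjusted p = 0.084). AT1G24040, an acetyltransferase of the GNAT family, rose from a mean log2 value of 0.84 ± 0.63 to 2.28 ± 0.26 (SD, n = 12 columns), a log2 change of 1.44 ± 0.20 (SE, adjusted p = 7.51e-06, 0.0075 averaged). The DEAD-box RNA helicase AT5G19210 rose by 1.62 ± 0.20 (adjusted p = 1.63e-06, 0.0041 averaged). Both were higher in all 12 numbers. AT4G17650, related to the coenzyme Q-binding protein COQ10, rose by 1.80 ± 0.33 (adjusted p = 0.00025, 0.0056 averaged) and was also higher in all 12 numbers. SRX, the plastid sulfiredoxin that reduces overoxidized peroxiredoxins, rose by 1.56 ± 0.48 (adjusted p = 0.014, higher in 11 of 12 numbers), and AT5G58410, the listerin-type ubiquitin ligase of ribosome quality control, by 1.72 ± 0.51 (adjusted p = 0.012). The log2 change of SRX was 0.70 in numbers 1 to 6 and 2.42 in numbers 7 to 12. That difference did not pass (limma interaction term on averaged values, adjusted p = 0.67). The pentatricopeptide repeat protein AT3G51320 rose by 1.85 ± 0.51 (adjusted p = 0.0077), and the AGC-type kinase AT3G44610 was 2.83-fold higher (adjusted p = 0.019). These 7 also passed with consecutive numbers averaged, SRX narrowly with an adjusted p of 0.049. Of the 7, AT3G51320 did not pass without the values at 0 (0.97, adjusted p = 0.15) or with a floor at the 5th percentile (0.81, adjusted p = 0.067), AT5G58410 did not without the values at 0 (1.16, adjusted p = 0.11), and SRX and AT3G44610 did not without normalization (adjusted p = 0.11 and 0.13). AT5G05330, AT5G49120, AT3G59300, AT5G06930 and the C2H2 zinc finger protein AT2G28200 did not pass with consecutive numbers averaged, where their adjusted p lay between 0.059 and 0.15. With the averaged sets paired by number 10 rises passed, all but AT5G49120 (adjusted p = 0.072) and AT5G06930 (adjusted p = 0.13). Leaving out the values at 0 ended the call for 6 of the 12 rises (AT5G05330, AT3G51320, AT5G49120, AT3G59300, AT5G58410 and AT2G28200), and 5 of the 12 passed without normalization, while the 12 falls passed in both cases. In numbers 1 to 6 alone 4 of the rises and 11 of the falls passed, and with 4 consecutive numbers averaged AT4G18180 alone of the 24.

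**Figure D3:**
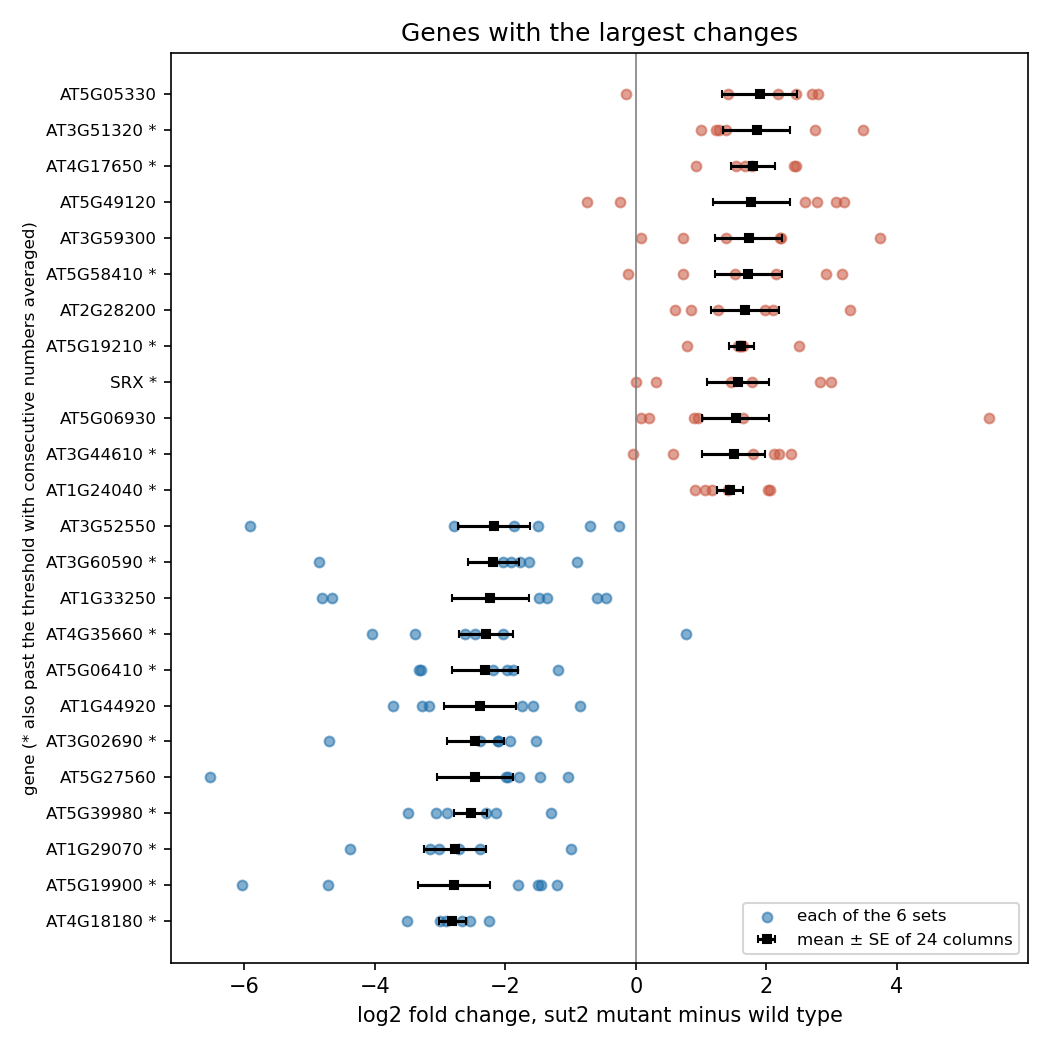
Log2 fold change (horizontal, sut2 mutant minus wild type) of the 12 named genes with the largest rises and the 12 with the largest falls. Black squares and bars are the mean and SE over 12 columns per group, coloured points the differences of the 6 sets of consecutive numbers, and an asterisk marks the 7 rises and 8 falls that also passed the threshold with consecutive numbers averaged.

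The pathways nearest to sucrose transport were hardly covered by the named probes. Of 21 gene lists fixed before the data were examined, 18 had no measured member. These were the sucrose transporters, monosaccharide and polyol transporters, starch metabolism, photorespiration, dark- and starvation-induced genes, phenylpropanoid synthesis, nitrogen assimilation, pathogen and jasmonate response, cold, drought and abscisic acid response, heat shock proteins, aquaporins and proton pumps, clock genes, cell wall expansion, reference genes, and the markers of flower, root, seed and vascular tissue. Tissue composition could therefore not be compared. From sucrose synthesis and cleavage 1 gene was measured. ATSPS4F, a sucrose-phosphate synthase, rose by 0.66 ± 0.21 (SE, adjusted p = 0.016) and was higher in all 12 numbers; its adjusted p was 0.13 with consecutive numbers averaged and 0.015 with the averaged sets paired by number. It did not pass without normalization (0.37, adjusted p = 0.16) or with array weights (0.38, adjusted p = 0.17). From the Calvin cycle, phosphoribulokinase (PRK) had a log2 change of -0.26 ± 0.12 (adjusted p = 0.11) and sedoheptulose-bisphosphatase (SBPASE) of 0.04 ± 0.16 (adjusted p = 0.87). Both passed as lower without normalization (PRK -0.62, adjusted p = 0.00096; SBPASE -0.46, adjusted p = 0.026). PRK also passed with cyclic loess (-0.35, adjusted p = 0.038), in numbers 7 to 12 alone (-0.43, adjusted p = 0.026) and without wild type number 1 (-0.31, adjusted p = 0.040). Of the photosynthetic light reactions 4 genes were measured and none passed, also none adjusted over the list alone: LHB1B2 (-0.27 ± 0.18), PSBY (0.15 ± 0.15), PSBW (0.09 ± 0.10) and PSAN (-0.08 ± 0.24). Other settings called 3 of them: LHB1B2 with probe position removed (-0.55, adjusted p = 0.014; 0.41 and not past with median centring), PSBY with median centring (0.66, adjusted p = 0.0029), and PSBW with median centring (0.78, adjusted p = 2.57e-06) and without normalization (0.24, adjusted p = 0.040). LHB1B2 belongs to a family of near-identical chlorophyll-binding proteins and its probe could read several of them. No difference of the list from the other genes passed the threshold (camera adjusted p = 0.87, 0.90 with an estimated correlation), and fry, which asks only whether members move one way on balance, gave an adjusted p of 0.96. The median log2 change of the list was 0.0049 and its mean -0.03, which differ in sign, and the median went from -0.32 with position removed to 0.57 with median centring.

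Further lists were drawn up from the genes named on the array, after the annotation was read and before any fold change was seen. Among 7 enzymes of central carbon metabolism, which include ATSPS4F, PRK and SBPASE, 3 rose and none fell. Besides ATSPS4F these were pyruvate orthophosphate dikinase, PPDK (0.90 ± 0.27, adjusted p = 0.012), and the lactate dehydrogenase AT4G17260 (0.43 ± 0.13, adjusted p = 0.015). None of the 3 passed with consecutive numbers averaged, with adjusted p of 0.13, 0.10 and 0.083, and AT4G17260 turned to -0.12 without normalization. PPDK changed by 0.24 in numbers 1 to 6 and 1.56 in numbers 7 to 12 (limma interaction term on averaged values, adjusted p = 0.59), and passed in 36 of 44 alternatives. Among 18 photosystem, electron transport and assembly proteins, which include the 4 above, 3 rose and 2 fell. LPA19, a photosystem II assembly factor, rose by 0.52 ± 0.11 (adjusted p = 0.00094), AT1G22700, a photosystem I assembly protein, by 0.68 ± 0.18 (adjusted p = 0.0054), and NdhN, a subunit of the plastid NDH complex, by 0.71 ± 0.20 (adjusted p = 0.0079). AT1G49380, a protein of cytochrome c biogenesis, fell by 1.35 ± 0.31 (adjusted p = 0.0018), and PSB27, named here after its values were seen, by 0.86 ± 0.29 (adjusted p = 0.024). AT1G49380 alone of the 5 also passed with consecutive numbers averaged (adjusted p = 0.032), and LPA19 passed with these averages paired by number (adjusted p = 0.044). Without normalization LPA19 (0.05, adjusted p = 0.82), AT1G22700 (0.19, adjusted p = 0.40) and NdhN (0.20, adjusted p = 0.47) did not pass. Of 5 enzymes of tetrapyrrole and carotenoid synthesis 1 rose. This was CHLM, the magnesium-protoporphyrin methyltransferase (2.64-fold, adjusted p = 0.041, 0.18 averaged), while Z-ISO (1.24 ± 0.50, adjusted p = 0.056) passed in 15 of 43 alternatives, among them the replicate number as a block (adjusted p = 0.032, but 0.13 with that block on averaged sets) and leaving out any 1 of wild type numbers 1, 2, 3, 4, 5 and 10 (adjusted p from 0.037 to 0.049). SIRB and HEMA3 had changes of -0.57 ± 0.55 and 0.14 ± 0.21. The call of CHLM was lost without any 1 of wild type numbers 9 to 12 and mutant numbers 1, 5, 6, 7 and 8, with log2 changes from 1.09 to 1.41 and adjusted p from 0.052 to 0.075.

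Of 5 plastid ribosomal proteins 2 fell, AT1G29070 and the S10 protein AT3G13120 (-1.33 ± 0.22, adjusted p = 7.22e-05), both also with consecutive numbers averaged; AT4G01310 (0.23 ± 0.24) and AT1G64510 (0.05 ± 0.37) did not pass. Of 19 pentatricopeptide repeat proteins, most of which act on organelle RNA, 6 rose and 3 fell, among them AT3G51320, AT5G39980, AT2G19280 (0.93 ± 0.22, adjusted p = 0.0027) and AT1G31790 (-1.17 ± 0.20, adjusted p = 0.00015). Averaging of consecutive numbers left 1 rise and 2 falls past the threshold. AT2G19280 had an adjusted p of 0.066 averaged and 0.019 with the averaged sets paired by number. The remaining fall was OTP85 (-0.38 ± 0.14, adjusted p = 0.041), named here after its values were seen, and the median of the list was 0.24, or -0.05 without normalization. Of 6 members of the mTERF family, which bind nucleic acids in organelles, 2 rose: AT5G55580, or mTERF9, by 0.85 ± 0.16 (adjusted p = 0.00025, 0.030 averaged) and AT1G79220 by 0.49 ± 0.17 (adjusted p = 0.025, log2 change -0.0087 without normalization). The latter had an adjusted p of 0.052 with the replicate number as a block, and with that block AT1G61990 (0.43 ± 0.17) and AT1G62010 (-0.37 ± 0.19) passed, with adjusted p of 0.047 and 0.020 in place of 0.055 and 0.13. With the block on averaged sets they did not (adjusted p = 0.15 and 0.12). AT1G61990 passed in 11 of 44 alternatives, among them those without wild type number 4 or 5 or mutant number 2 or 4 (adjusted p from 0.0085 to 0.044), and AT1G62010 also without normalization (-0.92, adjusted p = 0.00090) and without wild type number 5 (adjusted p = 0.033). Of 5 plastid fibrillins, proteins of plastid lipid bodies, 2 rose, AT2G35490 (0.83 ± 0.19, adjusted p = 0.0023) and AT2G46910 (0.89 ± 0.21, adjusted p = 0.0026). The former also passed averaged (adjusted p = 0.033), and both passed with the averaged sets paired by number (adjusted p = 0.024 and 0.025). Neither passed without normalization (0.34 and 0.47, adjusted p = 0.22 and 0.085). AT5G09820 (0.33 ± 0.31) and AT5G19940 (-0.45 ± 0.54) did not pass.

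None of the 10 added lists passed the threshold against the other genes by camera, where the smallest adjusted p was 0.58 and, with an estimated correlation, 0.90, and none had an unadjusted p under 0.05. By fry, which tests only whether the members of a list move one way on balance, 4 lists passed in the 24 columns: the plastid ribosomal proteins, lower (adjusted p = 0.00066), and the fibrillins (adjusted p = 0.0010), the mTERF family (adjusted p = 0.012) and the carbon metabolism enzymes (adjusted p = 0.025), all higher. The call of the plastid ribosomal proteins rests on AT1G29070 and AT3G13120: the mean of the 5 members was -0.77 and their median -0.00030, which was 0.09 with median centring and -0.45 without normalization. With consecutive numbers averaged, fry still called the plastid ribosomal proteins (adjusted p = 0.024) and the fibrillins (adjusted p = 0.020), but not the mTERF family (adjusted p = 0.10) or the carbon metabolism enzymes (adjusted p = 0.092). With the averaged sets paired by number the carbon metabolism enzymes passed (adjusted p = 0.011) and the mTERF family did not (adjusted p = 0.22). Without normalization between columns none of the 3 higher lists passed by fry (adjusted p from 0.090 to 0.68), and their median changes were -0.16, -0.06 and -0.12 instead of 0.39, 0.37 and 0.04. In that setting fry called the pentatricopeptide repeat proteins (adjusted p = 0.0040), the kinesins, histones and chromatin proteins (adjusted p = 0.020) and the transcription regulators (adjusted p = 4.54e-05) as lower, along with the plastid ribosomal proteins (adjusted p = 4.51e-07).

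The log2 change also varied with the place of a probe in the numbering of the probes. The numbers were read as 16 runs of 24 rows with 12 places each, an assumed layout that no label gives. Not every place held a tested probe. Row means of the change went from 0.34 in row 3 to -0.41 in row 20. With the position of each probe (its run, row and place in the row) removed from each column, 1083 probes passed, 881 of them among the 1196 with the same direction. The 12 largest rises and the 12 largest falls still passed, whereas ATSPS4F (0.33, adjusted p = 0.16), PPDK (0.63, adjusted p = 0.054) and CHLM (1.08, adjusted p = 0.11) did not.

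**Figure D4:**
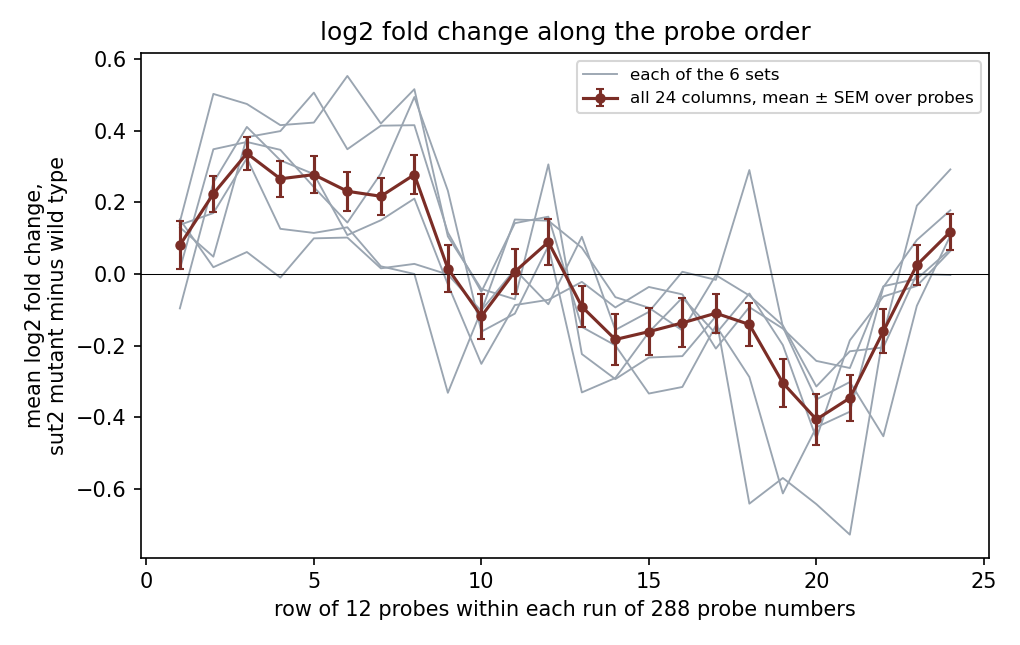
Mean log2 fold change (vertical, sut2 mutant minus wild type) of the probes in each of the 24 assumed rows of 12 places (horizontal), pooled over the 16 runs of probe numbers. The dark red line gives the mean and SEM over the probes of a row in all 24 columns, from 0.34 in row 3 to -0.41 in row 20, and grey lines give the means in each of the 6 sets of consecutive numbers.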

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

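The fits within or blocked by numbers 1 to 6 and 7 to 12, the averaged sets with a replicate block, fry with a block, averages or no normalization, and the removal of probe position were chosen after seeing the data. The other settings were planned, but the added gene lists were not, and so none of their tests was. The count of 1196 probes (648 higher, 548 lower) stayed within 1.5 times under the replicate block (1477), the random block, median centring, cyclic loess, both floors, both filters on dim probes, the trend and weight settings, and averaging of numbers 6 apart. Leaving out each of the 24 columns gave 1088 to 1227 probes, 581 to 674 higher and 505 to 553 lower. It fell to 449 (185 higher, 264 lower) with consecutive numbers averaged, 759 (354 higher, 405 lower) with these averages and a replicate block, 420 (171 higher, 249 lower) with probe position removed and averages taken, and 663 (305 higher, 358 lower) in numbers 1 to 6 alone, against 1099 in numbers 7 to 12 alone with as many columns; averaged, these gave 57 (4 higher, 53 lower) and 259 (79 higher, 180 lower). With 4 consecutive numbers averaged, 3 values per group, limma called 14 probes, 0 higher and 14 lower, and 770 had an unadjusted p under 0.05. If consecutive numbers are repeats, leaving out 1 column keeps its repeat in the fit, and averaging numbers 6 apart keeps both as separate values. The stable counts of such settings therefore do not test the count against repeats. Of the planned settings, only the averages of consecutive numbers, or of 4 of them, merge repeats. Without normalization 173 were higher and 1016 lower; with median centring 1053 were higher. Without the dimmest 50% of the probes, which leaves 1720 to test, 344 were lower. Where the number of samples or probes does not explain a difference, the cause was not tested.

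The planned gene list passed under none of 49 alternatives (smallest adjusted p 0.064). The added lists passed under none of 44 with camera (smallest adjusted p 0.32), while fry called 4 in the 24 columns, 4 with the replicate block, 2 with consecutive numbers averaged, 3 with these averages and the block, and 4 without normalization, of which 3 were others. There the medians of the pentatricopeptide repeat proteins (-0.050) and of the kinesins, histones and chromatin proteins (-0.26) turned from above to below 0. Of 2861 values of named genes under the alternatives, 2605 kept their side of the threshold, 206 lost the call and 47 gained it. Of the 2605, 43 values of 15 genes had the opposite sign with no call in either fit, 7 of them without normalization. In 3 more the sign turned with a call in 1 of the fits, each without normalization: SBPASE (-0.46), AT4G17260 (-0.12) and AT1G79220 (-0.0087). Among the 12 largest rises, 5 passed without normalization, 6 without a floor, 7 with consecutive numbers averaged, 8 in numbers 7 to 12 alone and 4 in numbers 1 to 6 alone. The 12 largest falls passed in these cases, except for 8 averaged and 11 in numbers 1 to 6. With 4 consecutive numbers averaged 1 of the 24 passed, the fall of AT4G18180. Of the 45 calls of named genes 22 were lost with consecutive numbers averaged, 19 in numbers 1 to 6 alone and 44 with 4 averaged, where fewer values are tested; the log2 changes of the 24 kept their sign. The replicate block ended 1 call and added 4, as given beside those genes, and changed no other call of a named gene or list. Restriction to probes with a value in all 24 columns removes none and was not run, quantile normalization as an alternative did not apply, gene lists were not run with the random block, and no alternative was possible for SUT2, which had no named probe. No signal over background is known for these values, so how far dim probes limit the calls was not measured beyond the filters.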

Other observations

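Tests on consecutive numbers, shared numbers, the 2 divisions of numbers and the share of calls kept without probe position were chosen after the result was seen; the splits of the columns, the profiles between sets and the Fisher test of genes near SUT2 in 24 columns were set beforehand, and the further checks of those genes were added after. Of 9 measured transcription regulators on an added list, 1 rose and 3 fell. AGL54, a MADS-box protein, rose from a mean log2 value of -1.53 to -0.53 (limma adjusted p = 0.0012), and AGL103, also a MADS-box protein, fell by 0.81 ± 0.12 (SE, adjusted p = 2.13e-05, lower in all 12 numbers). The homeodomain protein AT4G03090 fell by 1.14 ± 0.25 (adjusted p = 0.0011) and the bHLH protein AT1G27660 by 0.99 ± 0.31 (adjusted p = 0.016). All but AT1G27660 (adjusted p = 0.10, 0.044 with the averages paired by number) also passed with consecutive numbers averaged, and AGL54 did not pass without normalization (0.52, adjusted p = 0.11). The list did not pass the threshold against other genes by camera (adjusted p = 0.85, 0.95 with an estimated correlation).

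Of 12 kinesins, histones and chromatin proteins, the kinesin AT2G37420 fell by 0.75 ± 0.28 (adjusted p = 0.041) and the chromatin remodelling protein chr31 (AT1G05490) rose by 0.27 ± 0.10 (adjusted p = 0.042). Neither passed with consecutive numbers averaged (adjusted p = 0.15 and 0.27), and the kinesins AT3G20150 (0.54 ± 0.24) and AT3G44050 (-0.33 ± 0.15) did not pass. The former passed without wild type number 10 or mutant number 5 (adjusted p = 0.028 and 0.023). The latter passed without normalization (-0.86, adjusted p = 0.00012), in numbers 7 to 12 alone (-0.62, adjusted p = 0.028) and without wild type number 4 (adjusted p = 0.044). The call of AT2G37420 was lost without any 1 of wild type numbers 4, 5, 6, 7, 8 and 10 and mutant numbers 1, 2, 5, 7, 8, 9 and 10. That of chr31 was lost without any 1 of wild type numbers 5, 6, 7, 9, 10, 11 and 12 and mutant numbers 3, 4, 6, 11 and 12, with adjusted p up to 0.074 in both. None of 5 glycosyl hydrolases of family 9 and cellulose synthase-like proteins passed: GH9B8 had a change of -1.18 ± 0.61 (adjusted p = 0.14), GH9B12 of 0.74 ± 0.55 and GH9B16 of -0.34 ± 0.28. GH9B8 passed without wild type number 4 (adjusted p = 0.041), with numbers 6 apart averaged (adjusted p = 0.017) and without normalization (-1.62, adjusted p = 0.038), as did GH9B16 in the last case (-0.82, adjusted p = 0.021). CSLA01 (0.25 ± 0.20) passed with the replicate number as a block (adjusted p = 0.043), but not with that block on averaged sets (adjusted p = 0.22). Camera gave both lists an adjusted p of 0.94 (0.95 with an estimated correlation); the median of the second was 0.25, its mean -0.03. Both medians turned negative without normalization (-0.26 and -0.22).

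Of 100 splits of the 24 columns only the real one (1) gave as many as 1196, the highest other giving 353. Of 100 splits that parted all 12 numbers the same held (1), with 98 as the highest other. Both take the columns as exchangeable, which repeats of 1 sample would not be. They speak against chance only where every column is a sample of its own. The 32 splits of the averaged values that parted all 6 sets keep such repeats together. Of these only the real one (1) gave as many as 449, with 2 as the highest other. A share of 1 in 32 is the smallest that these splits can give. Chance is therefore unlikely but not excluded for that count, with the sets as samples. None of the splits bears on a dye effect that goes with the groups, or on differences between plants if the sets are technical repeats too.

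More probes passed with 24 columns than with 12 averaged values. In 24 of 24 columns the deviations from the group mean correlated best with the consecutive number of the same group, and in 24 of 24 with the same number of the other group. This is consistent with consecutive numbers being repeats of 1 sample, such as repeated spots or scans, and with the same numbers sharing an array as 2 colours. Under that reading the fit that matches is that of the averaged sets paired by number. It called 759 probes, 354 higher and 405 lower, against 449 unpaired. In simulated repeats on shared arrays 5.16% and 1.53% of such calls were false, and 8.90% of those from 24 columns. The simulations drew probes independently and held no effect of position, dye or the division of the numbers, so these shares may not carry over to the real calls. Separate plants handled together in consecutive numbers stay open, as the labels do not tell.

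Numbers 1 to 6 stood apart from 7 to 12 in both groups. The shift between the 2 divisions, taken in each group from different sets, correlated across probes by a median of 0.17 over 36 choices of sets, from 0.02 to 0.30. A swap of dyes would need an opposite shift in the groups, a correlation below 0, which none of the choices gave, and a batch shared by the groups would need correlations above 0.1. Since 27.8% of the choices lay below 0.1, the bounds set for excluding the swap and for accepting the batch were both missed. A swap would also put the dye effect into the difference of the change between the divisions. That limma interaction term called 5 probes in 24 columns and 1 averaged. The split that swaps the groups in numbers 7 to 12 called 0 and 1. These values argue against a swap with a large dye effect at many probes. A swap with a small dye effect, or a shared batch, may still contribute. If the same numbers do share an array, genotype and dye could not be separated without a swap, and that stays open.

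The log2 change followed the probe number. In the 16 runs of probe numbers, read as 24 rows of 12, the row means went from 0.34 in row 3 to -0.41 in row 20, and rows accounted for 7.09% of the variance of the change, against at most 0.60% in 100 shuffles. The row profiles correlated between the 6 sets by a median of 0.69 (0.44 to 0.91), which argues against uneven signal that differs from array to array. Of the 1196 probes, 73.7% still passed in the same direction with position removed, so run, row and place as added terms do not account for all calls. ATSPS4F (0.33, adjusted p = 0.16), PPDK (0.63, adjusted p = 0.054), CHLM (1.08, adjusted p = 0.11), AGL103 (-0.42, adjusted p = 0.067), AT2G37420 (-0.37, adjusted p = 0.37) and chr31 (0.05, adjusted p = 0.76) did not pass. A position effect of another form, or on a layout other than the assumed one, was not removed and may underlie calls that remain. A position effect common to all arrays and an uneven spread of gene content over the probe order both remain possible, and no biological explanation was tested.

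A linked segment that differs from the wild type around the mutation is a hypothesis that the named genes bear on. Of 12 measured genes with locus numbers AT2G01 to AT2G05, around SUT2 itself, 9 passed in the 24 columns, against 218 of 679 others (one-sided Fisher exact p = 0.0032). As many were held by 3 of 635 windows of 12 neighbouring measured genes. The 635 windows include the 12 genes themselves and windows that overlap them, so this count is not independent of the result. Of the 9, 6 were higher, among them AT2G03140 (1.07 ± 0.30), AT2G02590 (0.82 ± 0.14) and XERICO (0.49 ± 0.14), named here after their values were seen. With consecutive numbers averaged only AT2G02590 passed (adjusted p = 0.018; Fisher exact p = 0.80), and with probe position removed 5 did (p = 0.29). The median absolute moderated t of the 12 genes was above that of random genes with one-sided permutation p of 0.041 in 24 columns, 0.054 in the averaged values and 0.15 with position removed. The test set beforehand went with the hypothesis, but it rests on the 24 columns, which may be repeats. The later checks on averaged values, where 86 of the 679 others passed, and with position removed did not go with it. Both groups are given as the Wassilevskija ecotype, which by itself gives no source for such a segment. The hypothesis stays undecided.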
